A study of Mus musculus with 28 samples.

How the data were processed

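The deposited table holds 45101 probe sets of the Mouse430_2 array for 28 arrays, as GCRMA values by the notes of the authors, who give neither a version nor settings. The unit was read as log2, the scale GCRMA gives, since the authors do not state the base of the logarithm; array medians ran from 2.31 to 2.40 and highest values from 16.2 to 16.7. The raw image files were not used here.

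Probe sets were assigned to genes with the array annotation and the RefSeq gene table. Of the probe sets, 34958 name 1 gene, 932 several and 9211 none, and 64 are controls of the array maker. The brightest probe set naming 1 gene stood for a gene, which gave 18194 genes. The detection level was the mode of all values plus 2 log2 units, 4.27, and the 9872 genes over it in at least 2 arrays were tested.

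One linear model with a mean for each of the 14 groups was fitted to all 28 arrays with limma (lmFit and eBayes, 14 residual degrees of freedom), and 25 contrasts were tested, with the Benjamini-Hochberg method within each and a threshold of 0.05. These choices, the gene lists, the rule for naming genes and all alternatives except the actin covariate were made before the data were examined. The alternative fit with the replicate number within each cell type as a block (12 residual degrees of freedom) was among them. The labels do not say that equal replicate numbers belong together. The values do: sorted distributions of arrays with the same replicate number differed by 0.00372 to 0.0482 and those with different numbers by 0.194 to 0.273, and the sexes differed.

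The 30 gene lists were written from general knowledge, and 27 with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 27 lists and 4 contrasts. Camera with an estimated correlation and fry were alternatives. Genes of a list were counted with adjustment over all genes and adjusted over the list alone.

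Genes were named by rule, in each of the 4 middle-dose contrasts, among those with an adjusted p under 0.05, both drug arrays on the same side of both control arrays and a named symbol. The rule takes the 8 largest rises and falls with both means over the detection level. It takes up to 5 each way with 1 mean under that level, as bounds, and up to 4 called members of each list by size. For the drug difference, the response difference and the controls it takes the 5 largest each way. At other doses it takes genes already named, and a gene outside the rule is said to have been chosen after its values were seen.

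In a self-test with 200 changed genes in each of 10 simulations of 1 contrast, limma recovered 12.2% of 2-fold, 46.4% of 4-fold and 73.4% of 8-fold changes without the block, and 80.0%, 98.0% and 100% with it. No unchanged gene of 96470 was called without the block and 95 with it. The arrays were drawn from the fit with the block, with 1 shift between replicate numbers per cell type and independent noise, so these rates favour that fit. In the data the changes of replicate number 1 were larger (ratio of standard deviations 1.38 in CD4 cells with romidepsin at 10 nM), which the simulations leave out. R 4.3.3 and limma 3.58.1 were used.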

Results

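Romidepsin and vorinostat are inhibitors of histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The series asks how these drugs act directly on gene expression in T cells. Expression was measured on 28 mouse arrays, 14 of CD4 T cells and 14 of CD8 T cells taken from spleen by negative selection. The cells were stimulated for 2 days through CD3 and CD28 and then kept for 1 day with romidepsin at 2, 10 or 30 nM, with vorinostat at 0.5, 2 or 10 µM, or without drug (control). The labels name no vehicle for the control, so an effect of a vehicle cannot be set apart from that of a drug. Each of the 14 groups held 2 arrays, so n is 2 for every mean below, and ± is the standard error of a difference between groups. That number and the choice of fit both limit the precision. The 95% interval of a difference between 2 groups reached a median of 0.97 log2 units to each side, and 0.35 with the replicate number as a block. For the differences between the responses of the cell types it was 1.38, and 0.50 with the block. The ± values come from the fit without the block.

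Cd4 lay between 2.39 and 8.55 log2 units in the CD4 arrays and at most at 2.34 in the CD8 arrays. Cd8a lay between 9.34 and 11.99 in the CD8 arrays and at most at 6.07 in the CD4 arrays. In 3 CD4 arrays Cd4 lay under the detection level of 4.27 (2.39 with vorinostat at 10 µM in replicate 1, 2.75 and 4.14 with romidepsin at 30 nM), so only the low Cd8a and Cd8b1 (at most 7.08, against at least 9.93 in the CD8 arrays) support their label. Cd4 and Cd8a matched the label in the other arrays. The arrays of replicate number 1 differed from those of replicate number 2 in ways the labels do not state. Replicate 1 arrays held the Y-linked Eif2s3y at 11.36 to 12.02 and no Xist signal, and replicate 2 arrays held Xist, which silences an X chromosome in females, at 11.7 to 12.7 and no Eif2s3y signal. The lowest value was 2.2684 in every replicate 1 array and 2.2545 in every replicate 2 array, and the first principal component, with 41.2% of the variance, separated the replicate numbers. The replicate sets are therefore called batches 1 and 2 below. Whether they were normalized apart is not stated. Either way the replicate spread in a fit without the batch holds the batch difference, which widens its ± and lowers most counts. Both hold 1 array of each group, so the genes named first at each middle dose and the list medians are also given within each batch, and counts also from a fit with the batch as a block. For most other genes only the mean change is given. Where 1 array was left out the fit held no batch, so part of the batch difference entered the change. From 8447 to 9322 genes lay over the detection level per array. The 3' minus 5' difference of beta-actin, which grows as RNA degrades, lay between 0.75 and 1.62 log2 units and was largest with vorinostat at 10 µM in either batch. It was 1.62 and 1.09 there in CD4 cells in batches 1 and 2, against 0.94 and 0.78 in the controls, and 1.43 and 1.16 in CD8 cells, against 0.86 and 0.79. The same difference for Gapdh did not follow it throughout. With vorinostat at 10 µM it was 0.34 and 0.08 in CD4 cells in the batches, against 0.20 and 0.16 in the controls. In CD8 cells it was 0.26 and 0.13, against 0.20 and 0.08. The actin difference may therefore not stand for RNA quality alone.

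Romidepsin at 10 nM raised 624 genes in CD4 cells and lowered 229. Iigp1, an interferon-induced GTPase that acts against intracellular pathogens, rose by a log2 value of 5.35 ± 0.56 (adjusted p = 3.03e-05), by 6.12 and 4.58 in batches 1 and 2. H1f2, a linker histone, rose by 5.31 ± 0.71 (adjusted p = 0.000199), by 5.39 and 5.22 in the batches. Serpinf1, a secreted serpin that restrains blood vessel growth, changed by -4.31 ± 0.87 (adjusted p = 0.00498), by -5.59 and -3.02 in the batches. The other large rises between detected levels were in Acbd7 (4.61), Tex15 (4.25), Prkar2b (4.19), Bex1 (3.99), the neuronal tubulin gene Tubb2b (3.93) and Mpzl1 (3.76). The other large falls were in Asb2 (-3.60), the motor gene Myo6 (-3.24), the lipoprotein receptor gene Vldlr (-3.01), Emilin2 (-3.01), the cytokine Il24 (-2.92), the adaptor Dok2 (-2.71) and Trat1 (-2.68), which encodes a partner of the T cell receptor. From under the detection level, Npl rose at least 36.8-fold, Lrp11 at least 20.3-fold, Stx3 at least 14.5-fold, Wasf1 at least 11.5-fold and Fnbp1l at least 10.5-fold. To under it, Stc2 fell at least 14.2-fold, the costimulatory receptor Cd27 at least 12.8-fold, the cytokine Il5 at least 12.4-fold, the leukotriene receptor Cysltr1 at least 9.44-fold and Tgfb3 at least 7.77-fold.

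The T cell receptor, JAK-STAT, chemokine receptor and CD4 identity lists were lower in CD4 cells at 10 nM. The cytotoxic, exhaustion, naive and memory, lineage factor and effector cytokine lists were not called there. Of 22 T cell receptor signalling genes, 2 fell, Vav1 (-1.58) and Cd3e (-0.89), and 20 did not pass. The same 2-gene count held adjusted over the list alone, and with the block 13 fell and 2 rose. The list's median change was -1.10 (-1.36 and -0.68 in batches 1 and 2; limma camera adjusted p = 0.000709, adjusted p = 0.675 with an estimated correlation). Of 25 cytokine receptor and JAK-STAT genes, 3 fell, Il2rb (-1.41), Pim1 (-1.19) and Pim2 (-1.11), and also 3 adjusted over the list alone, against 14 down and 1 up with the block. Their median was -0.62 (-0.93 and -0.43 in the batches; adjusted p = 0.000651, adjusted p = 0.675 with an estimated correlation). Of 17 chemokine receptor and adhesion genes, the activation marker Cd69 rose by 2.29 and Ccr8 fell at least 1.68-fold, with the same counts adjusted over the list alone and 2 up and 8 down with the block. Their median was -1.20 (-1.61 and -0.61 in the batches; adjusted p = 0.0449, adjusted p = 0.675 with an estimated correlation). Of 6 CD4 identity genes, Trat1 and Cd4 fell, also adjusted over the list alone, and 3 fell with the block. Cd4 changed by -2.31 ± 0.67, by -3.72 and -0.90 in the batches, and the list's median was -1.14 (-1.17 and -0.76 in the batches; adjusted p = 0.0137, adjusted p = 0.269 with an estimated correlation; 0.174 with the block). Beside these lists, the actin 3' minus 5' difference was 1.33 and 0.85 in batches 1 and 2 with romidepsin at 10 nM, against 0.94 and 0.78 in the controls. With the block and that difference as a covariate none of these list calls held, and the T cell receptor median was -0.41.

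Genes of growth and survival were lower as well in CD4 cells at 10 nM. Among 24 mitosis genes, the mitotic kinase gene Plk1 fell (-1.38), with no call adjusted over the list alone and 22 down with the block. Their median was -0.87 (-0.95 and -0.82 in the batches; adjusted p = 7.18e-05, adjusted p = 0.675 with an estimated correlation). Among 25 DNA replication genes, Rrm2, which encodes a subunit of ribonucleotide reductase, fell (-1.42), with no call adjusted over the list alone and 1 up and 17 down with the block. Their median was -0.50 (-0.54 and -0.40; adjusted p = 0.00256, adjusted p = 0.70 with an estimated correlation). Among 24 MYC and ribosome biogenesis genes, Bop1 fell (-0.65), with no call adjusted over the list alone and 13 down with the block, at a median of -0.37 (-0.48 and -0.22; adjusted p = 0.00117, adjusted p = 0.474 with an estimated correlation). Of 18 glycolysis genes, 4 fell, among them Pfkl (-1.85), Slc16a3 (-1.56), which encodes a lactate exporter, and Tpi1 (-1.06), and the neuronal enolase gene Eno2 rose (1.96), with the same counts adjusted over the list alone and 2 up and 7 down with the block. Their median was -0.40 (-0.56 and -0.26; adjusted p = 0.0011, adjusted p = 0.428 with an estimated correlation). Of 11 anti-apoptotic genes, the caspase-8 inhibitor gene Cflar fell (-1.73), also adjusted over the list alone, and 9 fell with the block, at a median of -0.78 (-0.89 and -0.72; adjusted p = 0.000651, adjusted p = 0.478 with an estimated correlation).

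Groups that were higher in CD4 cells at 10 nM were neuronal and interferon response genes. Of 11 neuronal genes over the detection level, 5 rose and 6 did not pass (6 rose adjusted over the list alone, and 6 with the block). The kinesin gene Kif5c rose at least 10.2-fold, Bex1 by 3.99, Bex2 at least 3.66-fold and the synaptotagmin gene Syt11 by 2.28, and the list's median was 2.17 (2.12 and 2.20 in the batches; adjusted p = 2.6e-06, adjusted p = 0.0747 with an estimated correlation). Of 13 interferon response genes, Ifih1 (1.29), Irgm1 (1.19) and Igtp (1.14) rose and Ddx58, a sensor of viral RNA, fell (-1.57), against 6 up and 1 down adjusted over the list alone and 9 up and 2 down with the block. Their median was 0.51 (0.72 and 0.66 in the batches; adjusted p = 0.0297, adjusted p = 0.428 with an estimated correlation; 0.0994 with the block). None of 10 B cell markers passed alone or adjusted over the list alone, 5 fell with the block, and their median was -1.25 (-0.54 and -1.93 in the batches; adjusted p = 0.0275, adjusted p = 0.675 with an estimated correlation). The effector cytokine list was not called (adjusted p = 0.483). Of its 19 genes, Il5, Ltb (-2.64) and Il21 (-2.08, with another probe set of the gene of the opposite sign) fell and Tnf rose (1.97), against 1 up and 4 down adjusted over the list alone and 3 up and 4 down with the block. Its median was 0.44 while its mean was -0.09 and its test pointed down.

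With limma, 853 of 9872 genes passed in CD4 cells at 10 nM, and 73.2% of them rose. With the block 4759 passed, 2589 up and 2170 down (54.4% up), and all 853 were among them with 1 sign in both batches. Quantile normalization across all arrays gave 940 up and 558 down, and equal medians 801 up and 532 down. The count was 269 without romidepsin 10 nM replicate 1 and 280 without control replicate 1, and across genes, which are not independent replicates, the changes of the batches correlated at 0.851, those of batch 1 being larger (ratio of standard deviations 1.38).

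**Figure D1:**
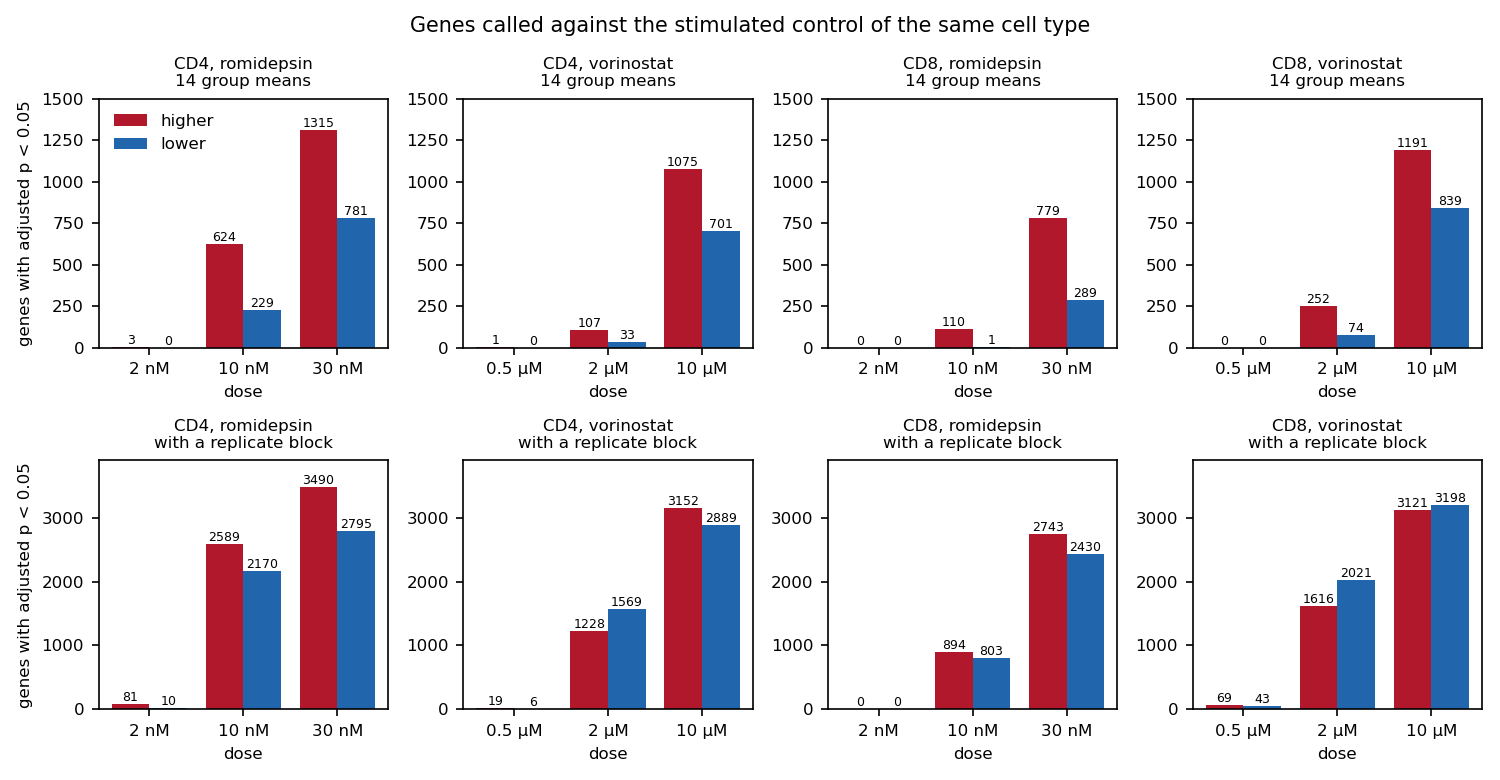
Genes passing adjusted p under 0.05 against the control (vertical axis, red bars for up and blue bars for down) at each dose of each drug in CD4 and CD8 cells, without and with the batch as a block. At 10 nM romidepsin CD4 cells had 624 genes up and 229 down, and CD8 cells 110 up and 1 down.

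Vorinostat at 2 µM raised 107 genes in CD4 cells and lowered 33. Tubb2b rose by 3.95 ± 0.60 (adjusted p = 0.00266), by 4.32 and 3.59 in batches 1 and 2. Mgst3, a membrane-bound glutathione enzyme, rose by 3.27 ± 0.30 (adjusted p = 2.65e-05), by 4.0 and 2.54 in the batches. Trib3, a pseudokinase induced by cell stress, changed by -2.65 ± 0.30 (adjusted p = 0.000214), by -3.11 and -2.19 in the batches. Further rises were in Acbd7 (3.34), Iigp1 (3.28), Tex15 (2.96), Armcx2 (2.78), Septin4 (2.72) and Eaf2 (2.58). Further falls were in the transcription factor gene Atf5 (-2.15), the phosphofructokinase gene Pfkl (-2.12), Trat1 (-1.81), Unc13d (-1.77), which acts in granule release, the glutathione-degrading Chac1 (-1.75), Espn (-1.70) and Ampd3 (-1.68). From under the detection level, Lrp11 rose at least 6.86-fold, Npl at least 5.42-fold, Kif5c at least 5.09-fold, Stx3 at least 4.83-fold and Kank3 at least 3.72-fold. To under it, Il5 fell at least 12.4-fold, Cysltr1 at least 9.44-fold, Nupr1 at least 2.83-fold, Zfp467 at least 2.07-fold and Mettl25 at least 2.05-fold.

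Of the neuronal genes, Kif5c and Bex1 (2.43) rose and 9 did not pass, against 3 up adjusted over the list alone and with the block, at a median of 0.63 (0.67 and 0.56 in the batches; adjusted p = 5.75e-05, adjusted p = 0.178 with an estimated correlation). Of the interferon response genes, Ifih1 rose (1.19), against 3 up adjusted over the list alone and 5 up and 1 down with the block. Their median was 0.32 (0.61 and 0.04 in the batches; adjusted p = 0.0209, adjusted p = 0.408 with an estimated correlation; 0.104 with the block). None of the mitosis or DNA replication genes passed alone or adjusted over the list alone, and 21 and 15 fell with the block. The mitosis median was -0.77 (-0.92 and -0.62; adjusted p = 1.13e-05, adjusted p = 0.675 with an estimated correlation). The DNA replication median was -0.50 (-0.65 and -0.37; adjusted p = 0.00159, adjusted p = 0.687 with an estimated correlation), and this call ended without vorinostat 2 µM replicate 1 (-0.01). That fit set an array of batch 2 against controls of both batches. None of the MYC and ribosome biogenesis genes passed either way, 9 fell with the block, and their median was -0.41 (-0.55 and -0.31; adjusted p = 5.75e-05, adjusted p = 0.395 with an estimated correlation). Of 16 cholesterol synthesis genes, Lss fell (-0.98), against 3 down adjusted over the list alone and 1 up and 7 down with the block, at a median of -0.45 (-0.48 and -0.51; adjusted p = 0.000906, adjusted p = 0.457 with an estimated correlation). Of the glycolysis genes, Pfkl fell, against 1 up and 1 down adjusted over the list alone and 2 up and 4 down with the block, at a median of -0.18 (-0.23 and -0.18; adjusted p = 0.0404, adjusted p = 0.675 with an estimated correlation; 0.249 with the block). Beside these groups, the actin 3' minus 5' difference was 1.19 and 0.85 in the batches with vorinostat at 2 µM, against 0.94 and 0.78 in the controls. Bmf (2.03) and the death receptor gene Fas (1.69), both pro-apoptotic, rose.

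With limma, 140 genes passed in CD4 cells with vorinostat at 2 µM, 76.4% of them up, and 2797 with the block, 1228 up and 1569 down, so the larger direction turned. Quantile normalization across all arrays gave 177 up and 106 down, and equal medians 196 up and 90 down. The count was 18 without vorinostat 2 µM replicate 1, 61 without its replicate 2 and 20 without control replicate 1. Across genes the changes of the batches correlated at 0.780.

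In CD8 cells, romidepsin at 10 nM raised 110 genes and lowered 1. Mpzl1, a surface glycoprotein, rose by 3.79 ± 0.78 (adjusted p = 0.0234), by 3.93 and 3.65 in batches 1 and 2. Marcks, a membrane-bound substrate of protein kinase C, rose by 3.24 ± 0.45 (adjusted p = 0.0016), by 3.49 and 3.00 in the batches. Further rises were in Septin4 (3.33), H1f2 (3.33), the actin-bundling Fscn1 (3.03), the zinc finger gene Plagl1 (2.98), Acbd7 (2.96) and the myosin gene Myh10 (2.74), and the fall was in Wdr13 (-0.98 ± 0.21). From under the detection level, Npl rose at least 16.5-fold, the desmosome gene Dsp at least 9.09-fold, Kif5c at least 7.09-fold, Dmxl2 at least 6.36-fold and Selenom at least 5.33-fold.

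Of the neuronal genes 4 rose and 7 did not pass (5 up adjusted over the list alone and with the block). They were Kif5c, Uchl1 (at least 2.85-fold), Bex1 (2.12) and Syt11 (1.81), and the list's median was 1.12 (1.66 and 0.82 in the batches; adjusted p = 7.89e-11, 0.0336 with an estimated correlation). Of the interferon response genes, Igtp rose (1.18), against 5 up adjusted over the list alone and 6 with the block, at a median of 0.75 (0.76 and 0.68; adjusted p = 6.01e-06, 0.0336 with an estimated correlation). Of the cytokine receptor and JAK-STAT genes, Socs3, a brake on cytokine signalling, rose (1.20), against 3 up adjusted over the list alone and 7 with the block, at a median of 0.33 (0.32 and 0.35; adjusted p = 0.00035, adjusted p = 0.675 with an estimated correlation). Of 22 T cell lineage transcription factors, Irf4 rose (1.10), against 5 up adjusted over the list alone and 6 up and 2 down with the block, at a median of 0.18 (0.21 and 0.25; adjusted p = 0.00228, adjusted p = 0.46 with an estimated correlation; 0.0817 with the block). Among effector cytokine and chemokine genes 1 rose adjusted over the list alone, 4 with the block and none over all genes. Their median was 0.50 (0.60 and 0.38; adjusted p = 0.0297, adjusted p = 0.675 with an estimated correlation), and this call ended without romidepsin 10 nM replicate 1 (-0.01) and without control replicate 2 (0.21). Those fits set an array of 1 batch against arrays of both.

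No member passed over all genes in the next 5 lists in CD8 cells at 10 nM, which the list test called. The MYC and ribosome biogenesis genes had a median of -0.55 (-0.66 and -0.49 in the batches; adjusted p = 7.89e-11, adjusted p = 0.0534 with an estimated correlation), with 2 down adjusted over the list alone and 12 with the block. The mitosis genes had a median of -0.56 (-0.78 and -0.39; adjusted p = 8.07e-05, adjusted p = 0.675 with an estimated correlation), with 0 adjusted over the list alone and 13 down with the block. The DNA replication genes had a median of -0.48 (-0.71 and -0.31; adjusted p = 5.75e-05, adjusted p = 0.675 with an estimated correlation), with 0 adjusted over the list alone and 12 down with the block. The 15 cell cycle inhibitors had a median of 0.42 (0.44 and 0.19; adjusted p = 0.00708, adjusted p = 0.528 with an estimated correlation; 0.101 with the block), with 0 adjusted over the list alone and 6 up with the block. Without control replicate 1 this call ended (0.39, adjusted p = 0.0517). The cholesterol synthesis genes had a median of -0.19 (-0.27 and -0.12; adjusted p = 0.0305, adjusted p = 0.675 with an estimated correlation; 0.129 with the block), with 0 adjusted over the list alone and 3 down with the block. That call ended without romidepsin 10 nM replicate 2 (-0.20, adjusted p = 0.293) and without control replicate 1 (-0.16, adjusted p = 0.513). The actin difference was 1.01 and 0.85 in the batches with romidepsin at 10 nM, against 0.86 and 0.79 in the CD8 controls.

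With limma, 111 genes passed in CD8 cells with romidepsin at 10 nM, 99.1% of them up, and 1697 with the block, 894 up and 803 down (52.7% up). Quantile normalization across all arrays gave 120 up and 23 down. The count was 15 without romidepsin 10 nM replicate 1, 32 without control replicate 1 and 62 without control replicate 2, and across genes the changes of the batches correlated at 0.740.

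In CD8 cells, vorinostat at 2 µM raised 252 genes and lowered 74. Ccl5, a chemokine of activated CD8 cells, rose by 4.34 ± 0.84 (adjusted p = 0.00914), by 5.28 and 3.41 in batches 1 and 2. The inflammatory cytokine Tnf rose by 3.29 ± 0.46 (adjusted p = 0.00078), by 3.67 and 2.91 in the batches. Bcat1, which breaks down branched-chain amino acids, changed by -3.13 ± 0.74 (adjusted p = 0.027), by -4.11 and -2.15 in the batches. Further rises were in Mpzl1 (3.97), Marcks (3.77), Acbd7 (3.59), Plagl1 (3.45), Septin4 (3.39) and the transporter gene Slc15a3 (3.37). Further falls were in Pfkl (-2.30), the folate enzyme gene Mthfd1l (-2.20), Dhrs4 (-2.16), Arl14ep (-2.10), Casd1 (-1.87), the folate carrier gene Slc19a1 (-1.83) and C1ql3 (-1.82). From under the detection level, Dsp rose at least 21.9-fold, Prss16 at least 11.4-fold, Npl at least 11.2-fold, Dmxl2 at least 7.83-fold and Tmcc3 at least 7.33-fold.

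The JAK-STAT, lineage factor, effector cytokine and interferon lists were higher with vorinostat in CD8 cells, while the cytotoxic and exhaustion lists were not called. Of 25 cytokine receptor and JAK-STAT genes 6 rose, among them Il12rb1 (2.54), Socs2 (2.46), the interleukin 2 receptor gene Il2ra (1.86) and Socs3 (1.78), also 6 adjusted over the list alone, and 11 up and 1 down with the block. Their median was 0.54 (0.59 and 0.55 in the batches; adjusted p = 3.26e-05, adjusted p = 0.562 with an estimated correlation). Of 22 lineage transcription factors 6 rose, also adjusted over the list alone, against 9 up and 2 down with the block. They included Tbx21 (2.24), which drives type 1 responses, Irf4 (1.72), Prdm1, a regulator of terminal differentiation (at least 3.94-fold), and Maf (at least 2.32-fold, with 1 of 3 other probe sets of the same sign). Their median was 0.42 (0.21 and 0.61; adjusted p = 0.0012, adjusted p = 0.451 with an estimated correlation; 0.0636 with the block). Of 19 effector cytokine and chemokine genes, Ccl5 and Tnf rose, also adjusted over the list alone, and 8 with the block. Their median was 0.81 (0.80 and 0.82; adjusted p = 0.0014, adjusted p = 0.562 with an estimated correlation), and the call ended without vorinostat 2 µM replicate 1 (0.16, adjusted p = 0.244) and without control replicate 2 (0.33, adjusted p = 0.182). Of 13 interferon response genes 5 rose, among them Gbp2 (2.78), Usp18 (1.55), Igtp (1.53) and Irgm1 (1.46), against 6 adjusted over the list alone and 8 up and 1 down with the block. Their median was 1.02 (1.5 and 0.51; adjusted p = 5.09e-06, 0.0336 with an estimated correlation). Beside these groups, the actin 3' minus 5' difference was 1.16 and 0.96 in batches 1 and 2, against 0.86 and 0.79 in the controls.

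Of 15 cell cycle inhibitors 4 rose, Gadd45g (2.64), Gadd45b (1.77), Cdkn1c (at least 1.84-fold) and Rb1 (0.90), also 4 adjusted over the list alone and 7 up and 1 down with the block. Their median was 0.44 (0.61 and 0.34 in the batches; adjusted p = 0.00256, adjusted p = 0.46 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 5 fell, among them Utp20 (-1.50), Srm (-1.40), Polr1b (-1.32) and Gnl3 (-1.14), against 11 adjusted over the list alone and 19 with the block, at a median of -0.75 (-0.94 and -0.61; adjusted p = 7.89e-11, adjusted p = 0.0534 with an estimated correlation). No mitosis or DNA replication gene passed over all genes, 1 mitosis gene fell adjusted over the list alone, and 19 and 18 fell with the block. The medians were -0.92 (-1.22 and -0.58) for mitosis genes (adjusted p = 3.26e-05, adjusted p = 0.675 with an estimated correlation) and -0.67 (-0.78 and -0.51) for DNA replication genes (adjusted p = 0.000106, adjusted p = 0.675 with an estimated correlation). Of the cholesterol synthesis genes, Insig1 (-1.18), a sterol sensor, and Lss (-0.95) fell, against 3 adjusted over the list alone and 7 with the block, at a median of -0.41 (-0.65 and -0.19; adjusted p = 0.000557, adjusted p = 0.443 with an estimated correlation). Of the neuronal genes 5 rose, among them Uchl1 (at least 3.58-fold), Bex2 (at least 3.52-fold), Kif5c (at least 6.49-fold) and Bex1 (1.68), also 5 adjusted over the list alone and 7 with the block. Their median was 1.44 (1.43 and 1.00; adjusted p = 3.13e-08, 0.0484 with an estimated correlation).

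With limma, 326 genes passed in CD8 cells with vorinostat at 2 µM, 77.3% of them up, and 3637 with the block, 1616 up and 2021 down, so the larger direction turned. Quantile normalization across all arrays gave 440 up and 248 down, and equal medians 413 up and 204 down. The count was 67 without vorinostat 2 µM replicate 1, 161 without its replicate 2, 77 without control replicate 1 and 162 without control replicate 2, and across genes the changes of the batches correlated at 0.820.

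**Figure D2:**
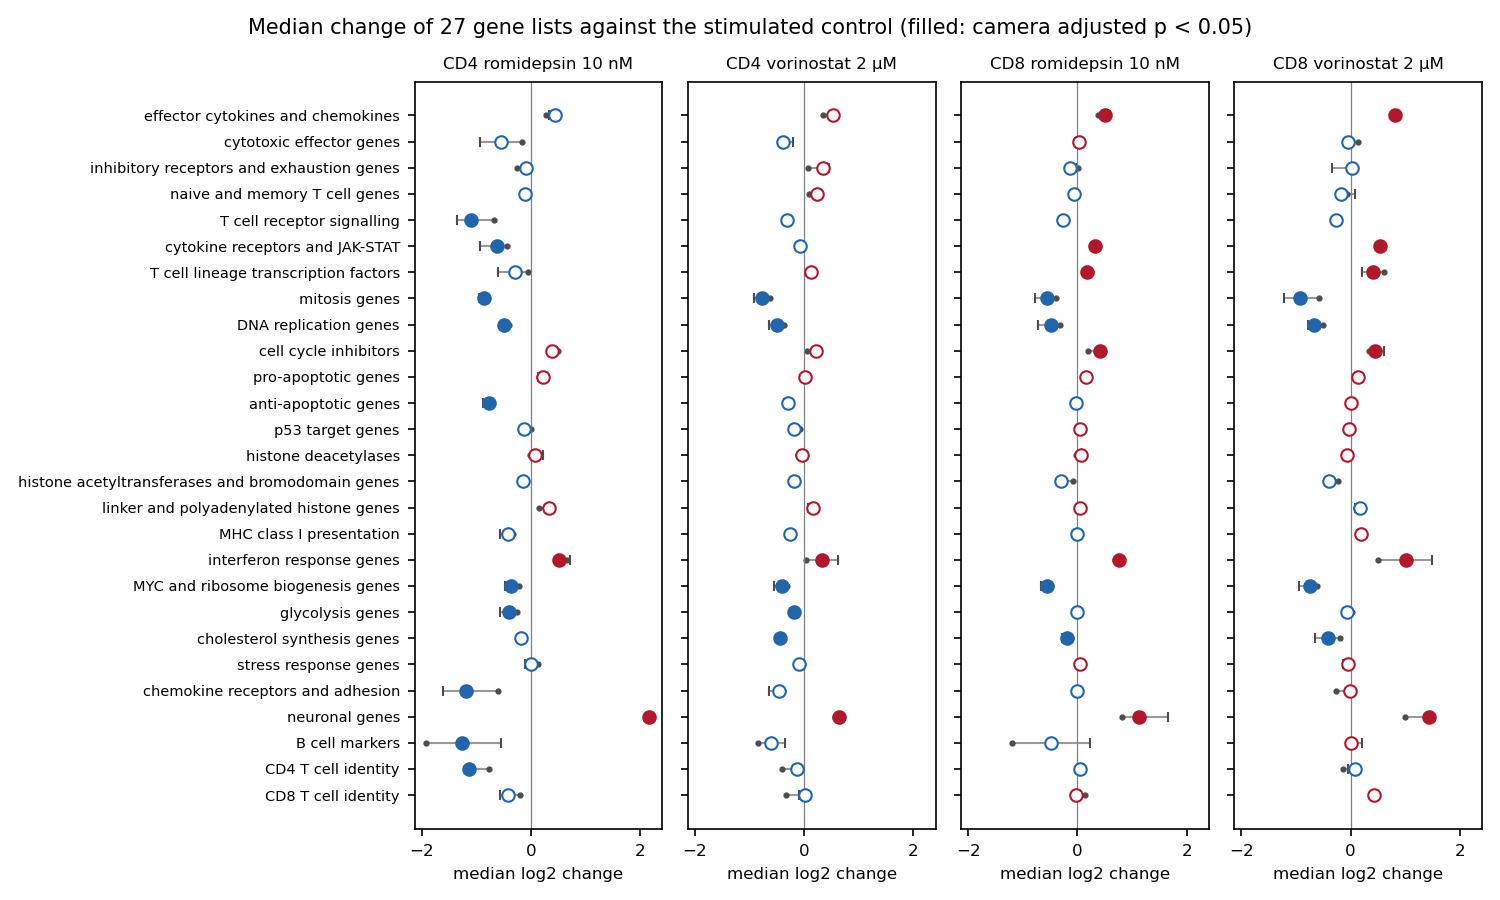
Median log2 change of each tested gene list against the control (horizontal axis) with romidepsin at 10 nM and vorinostat at 2 µM in CD4 and CD8 cells, as circles, red where the list test pointed up and blue where it pointed down, filled where called, with grey bars and dots for batches 1 and 2. Neuronal genes had medians of 2.17, 0.63, 1.12 and 1.44 (0.85, 0, 0.58 and 0.59 with means under the detection level set to it), and mitosis genes of -0.87, -0.77, -0.56 and -0.92.

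In none of the 4 middle-dose comparisons did the list test call 11 of the 27 lists, though single members passed. Pro-apoptotic genes (15, adjusted p of 0.0594 to 0.219) held 3, 2, 1 and 2 risen genes in the order above, among them Bmf at 2.70 and 2.03 in CD4 cells and 2.10 and 2.33 in CD8 cells, against 3, 2, 2 and 2 adjusted over the list alone. Stress response genes (23, 0.215 to 0.295) held Trib3 (-2.65 with either drug) and Chac1 (-1.84 and -1.75), which fell in CD4 cells, and Mt2 (1.93 and 2.73), Hspb1 and Mt1 (with another probe set of the opposite sign), which rose in CD8 cells. The heat shock gene Hspa1b rose in CD4 cells with romidepsin (2.96) and in CD8 cells with vorinostat (2.79), with the same counts adjusted over the list alone. Inhibitory receptor and exhaustion genes (17, 0.219 to 0.751) held Tox2 (2.59) and Vsir (-2.26), both in CD4 cells with romidepsin and also adjusted over the list alone. Naive and memory genes (16, 0.219 to 0.983) held Cd27, and p53 targets (17, 0.483 to 0.823) held Rrm2b (1.26) and Ercc5 (1.06), in the same cells, where 2 up and 3 down passed adjusted over the list alone. Of 16 cytotoxic effector genes (0.162 to 0.992) none passed over all genes or adjusted over the list alone, and at most 2 in a comparison fell with the block. Of 10 histone deacetylase genes (0.516 to 0.686), Hdac1 rose by 0.82 ± 0.17 in CD4 cells with romidepsin, also adjusted over the list alone. Of 17 acetyltransferase and bromodomain genes (0.0705 to 0.559), Crebbp changed by -1.28 in those cells, 1 up and 1 down adjusted over the list alone, and with the block the list was lower in CD8 cells with romidepsin (adjusted p = 0.046; 0.465 with an estimated correlation as well). Of 10 linker and polyadenylated histone genes (0.229 to 0.983) H1f2 rose with romidepsin. Of 15 MHC class I genes (0.107 to 0.915) the regulator gene Nlrc5 rose (1.16) and Tapbpl fell (-1.77) in CD4 cells with romidepsin, against 1 up and 2 down adjusted over the list alone. Of 9 CD8 identity genes (0.0726 to 0.983), Runx3 fell in CD4 cells with romidepsin (-1.12) and Ccl5 rose in CD8 cells with vorinostat, against 1 down and 2 up adjusted over the list alone.

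Members of these 11 lists that passed with the block follow, as up and down in the same order of comparisons. Pro-apoptotic genes had 6 and 3, 4 and 2, 3 and 1, and 4 and 2. For stress response genes the counts were 4 and 7, 5 and 6, 5 and 2, and 6 and 4, for exhaustion genes 3 and 4, 2 and 1, 0 and 0, and 3 and 3, and for naive and memory genes 2 and 2, 3 and 1, 0 and 0, and 1 and 1. They were 5 and 5, 2 and 2, 3 and 0, and 4 and 2 for p53 targets, 1 and 1, 0 and 2, 0 and 0, and 1 and 2 for cytotoxic genes, and 4 and 2, 1 and 1, 1 and 0, and 2 and 1 for histone deacetylases. Acetyltransferase and bromodomain genes had 2 and 6, 1 and 5, 1 and 5, and 1 and 10, and histone genes 4 and 1, 2 and 1, 1 and 0, and 2 and 1. MHC class I genes had 1 and 9, 1 and 6, 1 and 0, and 5 and 4, and CD8 identity genes 1 and 1, 0 and 0, 1 and 0, and 2 and 1.

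The lists called in some comparisons were not called in others, where single members also passed. In CD4 cells with romidepsin, the lineage factor genes Irf8 (2.83) and Hlf rose and Runx3 fell (adjusted p = 0.508 for the list), and the same genes counted adjusted over the list alone, against 2 up and 6 down with the block, so the larger direction turned. The cell cycle inhibitors Gadd45a (2.05), Cdkn1c and Rb1 (1.20) rose there, 5 adjusted over the list alone and 7 up and 3 down with the block (0.239), and of cholesterol synthesis genes Hsd17b7 rose (1.35) and Lss fell (-0.70, another probe set of opposite sign; 0.306; 3 up and 2 down with the block). With vorinostat in CD4 cells, T cell receptor (0.483), JAK-STAT (0.880), lineage factor (0.306), anti-apoptotic (0.229), chemokine receptor (0.376), B cell (0.361), CD4 identity (0.309), cell cycle inhibitor (0.117) and effector cytokine genes (0.608) were not called. With the block 2, 2, 2, 0, 1, 0, 0, 3 and 4 of them were up, and 3, 1, 1, 2, 4, 2, 1, 1 and 3 down. In CD8 cells T cell receptor genes (0.151 with romidepsin and 0.295 with vorinostat), glycolysis genes (0.947 and 0.229), anti-apoptotic genes (0.661 and 0.983), chemokine receptor genes (0.941 and 0.744), B cell markers (0.948 and 0.711) and CD4 identity genes (0.524 and 0.661) were not called. With romidepsin and the block 0, 1, 0, 2, 1 and 0 of them were up and 2, 1, 2, 1, 1 and 1 down, and with vorinostat 3, 3, 1, 3, 1 and 0 up and 5, 5, 2, 2, 2 and 1 down. Among glycolysis genes there, Pfkl and Tpi1 (-1.03) fell and Eno2 rose (1.69) with vorinostat, also adjusted over the list alone. The myeloid list and the erythroid and platelet list had 1 gene each over the detection level, Cd68 and Itgb3, and the NK cell list none, so these 3 were not tested.

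The list tests called 39 of 108, of which 4 held with an estimated correlation, 11 with fry and 31 with the block. With the block and an estimated correlation together none was called (0.137 to 0.297 for the 4). The detection filter left 11 of 32 listed neuronal genes, and a rise with drug can itself bring a gene past that filter. Without it the neuronal medians were 0 in CD4 cells with either drug, and 9.77e-05 and 0 in CD8 cells with romidepsin and vorinostat, and the calls held. The interferon medians were then 0.04, 0.05, 0.12 and 0.05 in the same order, against 0.51, 0.32, 0.75 and 1.02, and the first call ended (adjusted p = 0.0559). Part of each change can lie under the detection level, so medians were also taken with group means under that level set to it. The neuronal medians were then 0.85 and 0 in CD4 cells with romidepsin and vorinostat, against 2.17 and 0.63, and 0.58 and 0.59 in CD8 cells, against 1.12 and 1.44. In CD4 cells with romidepsin they were -0.99 rather than -1.10 for T cell receptor genes, -0.74 rather than -1.20 for chemokine receptor genes and -0.94 rather than -1.25 for B cell markers.

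With the block and the actin 3' minus 5' difference as a covariate, chosen after the results were seen, 10 of the 39 calls ended. In CD4 cells with romidepsin these were the T cell receptor (-0.41, adjusted p = 0.0837), JAK-STAT (-0.37, 0.0844), interferon (0.76, 0.0837), glycolysis (-0.13, 0.0837), chemokine receptor (-0.52, 0.0995) and CD4 identity lists (-0.74, 0.207). In CD4 cells with vorinostat they were the interferon (0.31, 0.111) and glycolysis lists (-0.10, 0.652), and in CD8 cells with romidepsin the cell cycle inhibitor (0.53, 0.0837) and cholesterol lists (-0.15, 0.0844).

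No called list differed in sign between its median, its mean and its test. Among lists not called, these signs differed in CD4 cells for effector cytokine and stress genes with romidepsin, CD8 identity genes with vorinostat and histone deacetylase genes with both drugs. They differed in CD8 cells with romidepsin for cytotoxic, MHC class I, glycolysis, CD4 identity and CD8 identity genes. With vorinostat they differed there for exhaustion, anti-apoptotic, p53 target, histone deacetylase, histone, MHC class I, stress, chemokine receptor, B cell and CD4 identity genes. In CD4 cells with romidepsin, the interferon call ended without romidepsin 10 nM replicate 1 (1.01, adjusted p = 0.0839) and without control replicate 2 (1.12, adjusted p = 0.0666). There the chemokine receptor call ended without romidepsin 10 nM replicate 1 (-0.39, adjusted p = 0.0907), its replicate 2 (-1.77, adjusted p = 0.0520), control replicate 1 (-1.36, adjusted p = 0.106) and CD8 vorinostat 2 µM replicate 1 (adjusted p = 0.0509). The glycolysis call ended without control replicate 1 (-0.30, adjusted p = 0.0917) and the B cell marker call without control replicate 2 (-0.23, adjusted p = 0.187). In CD4 cells with vorinostat, the interferon call ended without vorinostat 2 µM replicate 1 (0.43, adjusted p = 0.159) and control replicate 2 (0.66, adjusted p = 0.0666), and the glycolysis call without vorinostat 2 µM replicate 2 (-0.12, adjusted p = 0.738), control replicate 1 (-0.16, adjusted p = 0.895), CD8 romidepsin 10 nM replicate 1 (adjusted p = 0.0533) and its replicate 2 (adjusted p = 0.0507).

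The drugs were also set against each other at their middle doses, which are in different units and not matched in effect. In CD4 cells, Bcl3, which modulates NF-kappaB, was higher with vorinostat at 2 µM than with romidepsin at 10 nM by 1.46 ± 0.28. Lower with vorinostat were Npl (-2.76 ± 0.45), Abhd3 (-2.68), Specc1 (-2.25), Sestd1 (-1.89) and Coprs (-1.72). With limma 1 gene was higher and 33 lower, and with the block 411 were higher and 1110 lower. Quantile normalization gave 18 higher and 47 lower, and equal medians 3 and 19. The count was 6 without romidepsin 10 nM replicate 1, 7 without vorinostat 2 µM replicate 1 and 12 without its replicate 2. In CD8 cells no gene differed with limma (166 at an unadjusted p under 0.05, smallest adjusted p = 0.918), and with the block 18 were higher and 22 lower. The 95% interval of the difference lay within 2-fold for 37.8% of genes in CD8 cells (86.7% with the block) and 31.5% in CD4 cells (79.1% with the block), so a difference could not be ruled out for the others. Of the genes that passed with each drug in CD4 cells, 102 rose with both, against 6.76 for independent calls (1069 against 322 with the block). There 29 fell with both, against 0.765, and none moved in opposite directions (7 with the block). In CD8 cells 101 rose with both, against 2.81 (764 against 146), and 1 fell with both. Both drugs shared the same control arrays, which by itself makes changes correlate at 0.50 across genes in simulations without any effect. The observed correlations were 0.846 in CD4 cells and 0.892 in CD8 cells, and the covariance in CD4 cells was 0.413 against 0.0250 simulated.

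The response of CD8 cells was compared with that of CD4 cells by testing the difference between changes. For romidepsin at 10 nM, the test called 3 genes as more positive in CD8 cells and 4 as less. Gys1, the glycogen synthase of muscle and other tissues, changed by -1.67 in CD4 cells and by -0.05 in CD8 cells, a difference of 1.61 ± 0.27 (adjusted p = 0.0304; 1.62 and 1.61 in the batches). Its control mean was 8.63 in CD4 and 6.86 in CD8 cells, so CD4 cells fell toward the level that CD8 cells held without drug. The other genes called as more positive, Nupr1 and Espn, lay under the detection level in CD8 controls (2.57 and 3.18), so their fall in CD4 cells could not have appeared there, and no difference is given. Nupr1 was also the 1 gene called for vorinostat at 2 µM, which leaves no called gene whose difference could be measured there without the block. With the block, 353 genes were higher and 476 lower with romidepsin, and 113 and 30 with vorinostat. For romidepsin the split was 14 higher and 9 lower after quantile normalization and 10 and 6 with equal medians, so the larger direction turned. The romidepsin count of 7 was 3 without CD4 romidepsin 10 nM replicate 1, CD4 control replicate 1, CD8 romidepsin 10 nM replicate 2 or either CD8 control, and 12 without CD4 romidepsin 10 nM replicate 2. The vorinostat count was 0 without CD4 control replicate 1, either CD8 control or either CD8 vorinostat 2 µM array, 2 without CD4 vorinostat 2 µM replicate 2 and 3 without CD4 control replicate 2. Of the genes called in each cell type, 84 rose in both with romidepsin, against 6.95 for independent calls (669 against 234 with the block). With vorinostat 78 rose in both, against 2.73 (792 against 201), and 11 fell in both, against 0.247. None moved in opposite directions with either drug (25 and 27 with the block). The calls share each gene's variance, so they are not independent.

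Without drug, 239 genes were higher in CD8 than in CD4 cells and 375 lower. Higher were Ms4a4c (7.31 ± 0.95), Crtam (6.0), a receptor of cytotoxic T cells, Cd8a (5.76), the chemokine Ccl3 (5.70) and Eomes (5.52), a transcription factor of cytotoxic and memory cells. Lower were the transglutaminase gene Tgm2 (-8.33 ± 0.61), Ecm1 (-6.86), the cytokine Lif (-5.88), Frmd4b (-5.18) and Serpinf1 (-5.15). With the block, 2097 were higher and 1609 lower (56.6% higher, against 38.9% without it). Leaving out any 1 of the 4 arrays lowered the count of 614, to 297 without CD4 control replicate 1, 408 without CD4 control replicate 2, 311 without CD8 control replicate 1 and 342 without CD8 control replicate 2.

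The lowest doses changed few genes. In CD4 cells romidepsin at 2 nM raised 3 genes (159 at an unadjusted p under 0.05), among them Kif5c from under the detection level, and vorinostat at 0.5 µM raised 1 (110 unadjusted). In CD8 cells limma called no gene at either low dose (24 and 201 unadjusted), and with the block 0 and 112 (69 up, 43 down). With the block, the CD4 counts were 81 up and 10 down at 2 nM and 19 up and 6 down at 0.5 µM. The CD4 counts were 0 without CD4 control replicate 1 with either drug, 0 without romidepsin 2 nM replicate 1 or either vorinostat 0.5 µM array, and 7 and 6 without CD4 control replicate 2.

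At the highest doses many genes changed. Iigp1 rose by 6.69 ± 0.56 in CD4 cells at 30 nM romidepsin and by 6.52 at 10 µM vorinostat, and by 4.17 and 4.80 in CD8 cells. H1f2 rose by 5.28 and 4.52 in CD4 cells and by 4.23 and 4.09 in CD8 cells. Cd27 fell to under the detection level in CD4 cells with either drug, at least 12.8-fold, and changed by -4.20 (-5.91 and -2.49 in batches 1 and 2) and -5.41 (-6.33 and -4.49) in CD8 cells. Tnf rose by 3.01 and 2.62 in CD8 cells, while in CD4 cells it rose with vorinostat (1.75) and its change of 1.33 with romidepsin did not pass. In CD4 cells romidepsin at 30 nM raised 1315 genes and lowered 781 (3490 and 2795 with the block), and vorinostat at 10 µM raised 1075 and lowered 701 (3152 and 2889). In CD8 cells the counts were 779 and 289 for romidepsin (2743 and 2430 with the block, 53% rather than 72.9% up; 1099 and 692 after quantile normalization, 1033 and 727 with equal medians) and 1191 and 839 for vorinostat (3121 and 3198). The CD4 counts of 2096 and 1776 fell to 1075 and 887 without control replicate 1, and to 1156 and 948 without replicate 1 of the drug group. The CD8 counts of 1068 and 2030 were 421 and 1090 without control replicate 1, 421 and 1104 without replicate 1 of the drug group, and the first was 707 without control replicate 2. Actin 3' minus 5' differences in CD4 cells at 30 nM were 1.55 and 0.97 in batches 1 and 2, against 0.94 and 0.78 in the controls. In CD8 cells they were 1.23 and 0.90 at 30 nM and 1.43 and 1.16 at 10 µM in batches 1 and 2, against 0.86 and 0.79 in the controls.

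**Figure D3:**
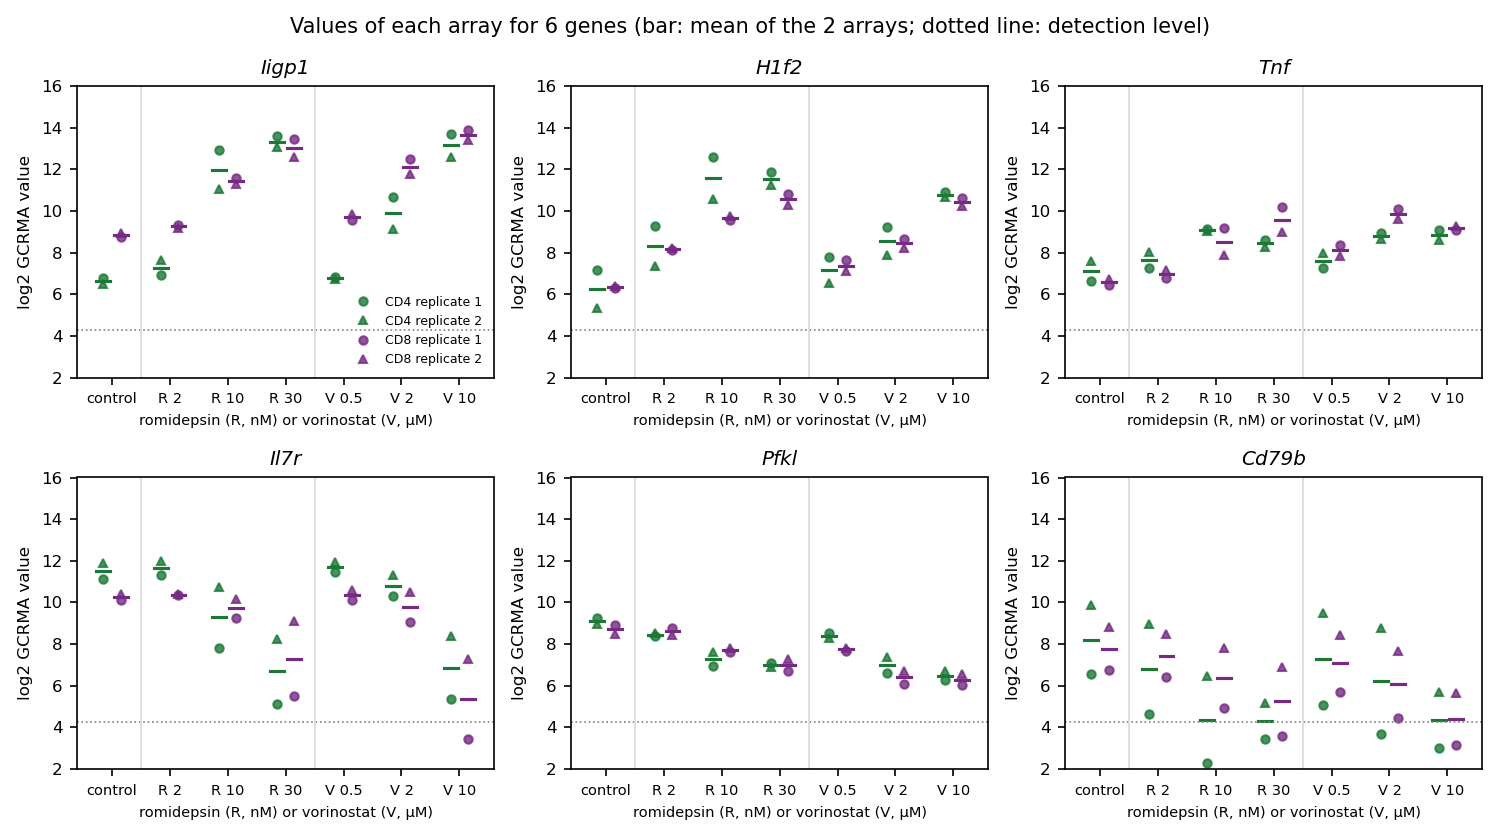
Log2 values of Iigp1, H1f2, Tnf, Il7r, Pfkl and Cd79b in every array (vertical axis) by dose, with CD4 and CD8 cells and batches 1 and 2 marked, the means as lines and the detection level dotted. These genes were chosen after their values were seen, and Iigp1 rose by 5.35 in CD4 cells at 10 nM romidepsin.

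Between neighbouring doses the steps were tested themselves. In CD4 cells, going from 2 to 10 nM romidepsin raised 322 genes and lowered 100 (2188 up and 1761 down with the block). The step from 10 to 30 nM raised 11 and lowered 1 (635 up and 421 down). Going from 0.5 to 2 µM vorinostat lowered 1 gene, and with the block 279 rose and 239 fell, so the larger direction turned. The step from 2 to 10 µM raised 361 and lowered 174 (2552 up and 1761 down). In CD8 cells the romidepsin steps raised 21 and 46 genes and lowered none without the block. With it they gave 327 up and 194 down, and then 1263 up and 789 down. The vorinostat steps there raised 16 (729 up and 507 down with the block) and then raised 303 and lowered 179 (2247 up and 1839 down). After quantile normalization the CD4 romidepsin steps gave 504 up and 288 down and then 10 and 4, and with equal medians 431 and 264 and then 4 and 1. The CD8 step from 10 to 30 nM gave 43 up and 10 down after quantile normalization and 26 and 3 with equal medians, and the CD8 step to 2 µM gave 23 and 7, and 12 and 2. With equal medians the steps to 10 µM gave 535 up and 446 down in CD4 cells and 449 each way in CD8 cells.

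Leaving out arrays moved the steps as well. The step from 2 to 10 nM gave 60 and 90 CD4 genes without replicate 1 of either dose and 209 without romidepsin 2 nM replicate 2, and the step to 30 nM gave 20 without romidepsin 30 nM replicate 2. The last vorinostat step gave 78 and 276 CD4 genes without replicates 1 and 2 at 10 µM and 94 and 197 without those at 2 µM. In CD8 cells the first romidepsin step gave 4 without romidepsin 10 nM replicate 1 and 6 and 9 without the 2 nM replicates. The next step gave 24 and 2 without the 10 nM replicates and 6 and 71 without the 30 nM replicates. The CD8 vorinostat steps gave 3 without replicate 1 of either lower dose and 5 without 2 µM replicate 2, and then 64 without 10 µM replicate 1 and 94 and 120 without the 2 µM replicates. For the CD4 step to 2 µM, leaving out an array of batch 1 gave 0 genes and an array of batch 2 gave 2.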

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

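The tests of the differences between list responses, and every test weighed below except the one on a lower dose, were chosen after the results were seen.

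A limma test of the difference between the responses, CD8 minus CD4, called the genes here. With romidepsin at 10 nM, Gys1 differed by 1.61 ± 0.27 (adjusted p = 0.0304). The gene 1500009L16Rik differed by -3.71 ± 0.47 (0.00232), 1700061F12Rik by -2.84 ± 0.22 (8.95e-06), Fmnl2 by -2.99 ± 0.44 (0.0117) and Tmem30b by -2.66 ± 0.42 (0.0180). Control means were 4.46 in CD4 and 9.28 in CD8 cells for 1500009L16Rik, and 8.63 and 6.86 for Gys1. In both genes the drug moved CD4 cells toward the level of the CD8 controls. In CD8 controls Fmnl2 (2.26), Tmem30b (2.26) and 1700061F12Rik (2.27) lay under the detection level, so their fitted differences are not bounds. Espn (3.18) and Nupr1 (2.57) also lay under it there, and their fall in CD4 cells could not have appeared in CD8 cells. Their fitted differences, 2.58 ± 0.44 for Espn (0.0320) and 3.54 ± 0.45 for Nupr1 (0.00232), and 3.09 ± 0.45 for Nupr1 with vorinostat at 2 µM (0.0386), were set by that limit and show no difference in response.

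Lists were tested the same way with camera, 23 of 54 passing, 2 with an estimated correlation and 21 with the block, and those that passed with and without the block follow. With romidepsin at 10 nM the median difference was 0.66 for T cell receptor genes (adjusted p = 0.00239; 0.648 with an estimated correlation), 1.29 for JAK-STAT genes (2.49e-13; 0.15), 0.78 for lineage factors (0.0010; 0.260) and 0.85 for anti-apoptotic genes (8.34e-05; 0.260). It was 0.38 for effector cytokines (0.00173; 0.406), 0.33 for MHC class I genes (0.0408; 0.731), 0.46 for glycolysis genes (2.31e-05; 0.15) and 0.47 for stress genes (0.000197; 0.121). It was 0.92 for chemokine receptors (0.0118; 0.406) and 0.80 for B cell markers (0.00745; 0.560).

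With vorinostat at 2 µM the median difference was 0.66 for effector cytokines (adjusted p = 2.31e-05; 0.246 with an estimated correlation), 0.81 for JAK-STAT genes (2.62e-11; 0.171), 0.43 for lineage factors (0.000254; 0.240) and 0.27 for MHC class I genes (0.0408; 0.731). It was 0.64 for interferon response genes (2.31e-05; 0.0440), -0.33 for MYC and ribosome biogenesis genes (1.27e-05; 0.171), 0.37 for stress genes (2.97e-07; 0.0382) and 0.47 for neuronal genes (0.0136; 0.372).

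With the block, 829 genes responded differently to romidepsin at 10 nM in CD8 and CD4 cells. Against CD8 cells at 30 nM, 246 of them (29.7%) still differed in the same direction and 583 no longer did. That comparison shares 3 of its 4 groups with the one that selected the genes, and no value without an effect was worked out, so a lower effective dose in CD8 cells stays open for all of them. With the actin 3' minus 5' difference as a covariate 100% kept at least 0.5 of their size (smallest ratio 0.756). With the drug the actin difference rose from 0.94 to 1.33 in batch 1 and from 0.78 to 0.85 in batch 2 of the CD4 cells. In CD8 cells it rose less, from 0.86 to 1.01 and from 0.79 to 0.85. The genes were picked by the same fit with the block, so the test is not independent of their choice. That outcome does not settle whether RNA quality plays a part. Whether the cell types differ in more than effective dose or RNA quality stays open.

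T cell receptor signalling genes had a median of -1.10 in CD4 cells with romidepsin at 10 nM, -1.36 and -0.68 in batches 1 and 2. With the block and the actin covariate the median was -0.41 (adjusted p = 0.0837). That covariate rose with the drug, so a part of RNA quality stays open. A lower share of T cells would raise markers of other cells, but 10 of 10 tested B cell markers had lower means in the treated arrays. Of the myeloid, NK, erythroid and platelet markers only Cd68 (6.37 in the control, 6.81) and Itgb3 (6.20, 4.75) passed the detection filter. These values go against a lower share of T cells. An action of the drug on the markers themselves was not tested, so that share was not excluded. A stronger action of the drug in batch 1, where the actin difference also rose most, stays open. The 3' minus 5' difference of Gapdh was 0.22 and 0.11 in the batches with romidepsin at 10 nM, against 0.20 and 0.16 in the controls.

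B cell markers over the detection level lay lower in both batches for 8 of 8 in CD4 cells with romidepsin at 30 nM, among them Cd79b (8.22 in the control, 4.31) and Ighm (8.52, 4.30). Loss of B cells left after the negative selection is a candidate explanation there. The list's Cr2, Ciita and Pax5 lay under the detection level in every array, which goes against it. Cd79a and Blk passed that level in 1 array each, with their highest means in the CD4 control. The source of the Cd79b and Ighm signal stays open. In CD8 cells 3 of 7 lay lower in both batches. Cd79b (7.79, 5.25) and Ighm (9.62, 4.96) had lower means there too, while the MHC class II genes Cd74 (7.73, 8.98) and H2-Ab1 (8.25, 9.19) had higher ones. A loss of B cells may therefore apply to the first pair, but by itself would not raise the second. T cells were not tested for these genes apart from B cells, so a change within T cells stays open in both.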

How the results depend on the processing

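The alternative with the actin covariate was chosen after seeing the data, and the other tests here were planned before. Counts are given below where they left the range within 1.5 times the count without that setting. The cause was not tested, except where fewer genes or arrays were used by construction. A minimum 2-fold change left all counts within that range. Where 1 array of a group was left out, the lone array was assumed to vary like the other groups. These fits held no batch, so the lone array was compared with arrays of both batches. Part of the batch difference then entered the change, and a moved count need not mean dependence on the array left out.

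With the batch as a block, the counts in CD4 cells were 91 for romidepsin 2 nM, 4759 for romidepsin 10 nM, 6285 for romidepsin 30 nM, 3949 for romidepsin 10 against 2 nM, 1056 for romidepsin 30 against 10 nM, 25 for vorinostat 0.5 µM, 2797 for vorinostat 2 µM, 6041 for vorinostat 10 µM, 518 for vorinostat 2 against 0.5 µM, 4313 for vorinostat 10 against 2 µM and 1521 for the drug difference. CD8 cells had 1697 for romidepsin 10 nM, 5173 for romidepsin 30 nM, 521 for romidepsin 10 against 2 nM, 2052 for romidepsin 30 against 10 nM, 112 for vorinostat 0.5 µM, 3637 for vorinostat 2 µM, 6319 for vorinostat 10 µM, 1236 for vorinostat 2 against 0.5 µM, 4086 for vorinostat 10 against 2 µM and 40 for the drug difference. Between cell types 829 for the romidepsin response difference, 143 for the vorinostat response difference and 3706 for the controls were called.

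With the mean of all probe sets of a gene, the counts in CD4 cells were 0 for romidepsin 2 nM, 5 for romidepsin 30 against 10 nM and 20 for the drug difference. CD8 cells had 64 for romidepsin 10 nM, 4 for vorinostat 0.5 µM and 7 for vorinostat 2 against 0.5 µM. Between cell types 0 for the vorinostat response difference were called.

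Without a filter on dim genes, the counts in CD4 cells were 9 for romidepsin 2 nM, 36 for romidepsin 30 against 10 nM, 6 for vorinostat 0.5 µM, 2 for vorinostat 2 against 0.5 µM and 71 for the drug difference. CD8 cells had 1 for romidepsin 2 nM, 91 for romidepsin 30 against 10 nM, 2 for vorinostat 0.5 µM and 1 for the drug difference. Between cell types 23 for the romidepsin response difference and 13 for the vorinostat response difference were called.

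With the strict filter, the counts in CD4 cells were 2 for romidepsin 30 against 10 nM, 2 for vorinostat 0.5 µM, 0 for vorinostat 2 against 0.5 µM and 20 for the drug difference. CD8 cells had 29 for romidepsin 30 against 10 nM. Between cell types 1 for the romidepsin response difference and 0 for the vorinostat response difference were called.

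After quantile normalization across all arrays, the counts in CD4 cells were 0 for romidepsin 2 nM, 1498 for romidepsin 10 nM, 792 for romidepsin 10 against 2 nM, 0 for vorinostat 0.5 µM, 283 for vorinostat 2 µM, 2743 for vorinostat 10 µM, 2 for vorinostat 2 against 0.5 µM, 1107 for vorinostat 10 against 2 µM and 65 for the drug difference. CD8 cells had 1791 for romidepsin 30 nM, 5 for romidepsin 10 against 2 nM, 2 for vorinostat 0.5 µM, 688 for vorinostat 2 µM, 30 for vorinostat 2 against 0.5 µM and 974 for vorinostat 10 against 2 µM. Between cell types 23 for the romidepsin response difference, 0 for the vorinostat response difference and 994 for the controls were called.

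With equal medians, the counts in CD4 cells were 1 for romidepsin 2 nM, 1333 for romidepsin 10 nM, 695 for romidepsin 10 against 2 nM, 5 for romidepsin 30 against 10 nM, 286 for vorinostat 2 µM, 2705 for vorinostat 10 µM, 0 for vorinostat 2 against 0.5 µM, 981 for vorinostat 10 against 2 µM and 22 for the drug difference. CD8 cells had 1760 for romidepsin 30 nM, 29 for romidepsin 30 against 10 nM, 2 for vorinostat 0.5 µM, 617 for vorinostat 2 µM and 898 for vorinostat 10 against 2 µM. Between cell types 16 for the romidepsin response difference, 2 for the vorinostat response difference and 924 for the controls were called.

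With a trended, robust prior, the counts in CD4 cells were 1 for romidepsin 30 against 10 nM, 2 for vorinostat 0.5 µM, 0 for vorinostat 2 against 0.5 µM and 18 for the drug difference. CD8 cells had 19 for romidepsin 30 against 10 nM. Between cell types 3 for the romidepsin response difference and 0 for the vorinostat response difference were called.

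With array weights, the counts in CD4 cells were 2 for vorinostat 0.5 µM. Between cell types 2 for the vorinostat response difference were called.

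Fitting the arrays of 1 cell type alone, the counts in CD4 cells were 0 for romidepsin 2 nM, 539 for romidepsin 10 nM, 147 for romidepsin 10 against 2 nM, 0 for romidepsin 30 against 10 nM, 0 for vorinostat 0.5 µM, 45 for vorinostat 2 µM, 0 for vorinostat 2 against 0.5 µM, 159 for vorinostat 10 against 2 µM and 11 for the drug difference. CD8 cells had 47 for romidepsin 10 nM, 0 for romidepsin 10 against 2 nM, 0 for romidepsin 30 against 10 nM, 120 for vorinostat 2 µM, 2 for vorinostat 2 against 0.5 µM and 168 for vorinostat 10 against 2 µM.

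Fitting the compared groups alone, the counts between cell types were 0 for the romidepsin response difference, 0 for the vorinostat response difference and 21 for the controls.

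With the block and the actin 3' minus 5' difference as a covariate, an alternative chosen after seeing the data, the counts in CD4 cells were 205 for romidepsin 2 nM, 3905 for romidepsin 10 nM, 4011 for romidepsin 30 nM, 2286 for romidepsin 10 against 2 nM, 552 for romidepsin 30 against 10 nM, 56 for vorinostat 0.5 µM, 2904 for vorinostat 2 µM, 2678 for vorinostat 10 µM, 520 for vorinostat 2 against 0.5 µM, 1569 for vorinostat 10 against 2 µM and 1942 for the drug difference. CD8 cells had 1 for romidepsin 2 nM, 2196 for romidepsin 10 nM, 4565 for romidepsin 30 nM, 844 for romidepsin 10 against 2 nM, 1684 for romidepsin 30 against 10 nM, 465 for vorinostat 0.5 µM, 3645 for vorinostat 2 µM, 3863 for vorinostat 10 µM, 1468 for vorinostat 2 against 0.5 µM, 2697 for vorinostat 10 against 2 µM and 134 for the drug difference. Between cell types 1081 for the romidepsin response difference, 423 for the vorinostat response difference and 4433 for the controls were called.

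Leaving out 1 array at a time, the counts in CD4 cells ran from 0 to 7 for romidepsin 2 nM, 269 to 742 for romidepsin 10 nM, 1075 to 1613 for romidepsin 30 nM, 60 to 379 for romidepsin 10 against 2 nM, 9 to 20 for romidepsin 30 against 10 nM, 0 to 6 for vorinostat 0.5 µM, 18 to 112 for vorinostat 2 µM, 887 to 1382 for vorinostat 10 µM, 0 to 2 for vorinostat 2 against 0.5 µM, 78 to 276 for vorinostat 10 against 2 µM and 6 to 40 for the drug difference. In CD8 cells they ran from 0 to 0 for romidepsin 2 nM, 15 to 94 for romidepsin 10 nM, 421 to 940 for romidepsin 30 nM, 4 to 29 for romidepsin 10 against 2 nM, 2 to 71 for romidepsin 30 against 10 nM, 0 to 0 for vorinostat 0.5 µM, 67 to 162 for vorinostat 2 µM, 1090 to 1592 for vorinostat 10 µM, 3 to 11 for vorinostat 2 against 0.5 µM, 64 to 325 for vorinostat 10 against 2 µM and 0 to 0 for the drug difference. Between cell types they ran from 3 to 12 for the romidepsin response difference, 0 to 3 for the vorinostat response difference and 297 to 408 for the controls.

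The list tests called 39 in all, 4 with an estimated correlation and 11 with fry, and 31 to 45 under the other alternatives. Leaving out 1 array gave 36 (without CD4 control replicate 1) to 40 (without CD4 romidepsin 10 nM replicate 2). The effector cytokine median in CD8 cells with romidepsin at 10 nM turned to -0.00859 without romidepsin 10 nM replicate 1, though it was positive within each batch. The batch difference may therefore account for that turn. Of 933 values of named genes none changed sign under any alternative, and with the block all stayed past the threshold. Of them 124 lost it after quantile normalization, 153 with equal medians, 170 of 918 with mean probe sets, 64 without a filter, 66 with the actin covariate, 39 with the robust prior and 21 with array weights. Fits of 1 cell type lost 244 of 866, fits of the compared groups 58 of 67, and leaving out 1 array 1205 of 3748. Of the 39 list calls, 8 ended with the block, 8 with equal medians, 4 after quantile normalization, 4 with mean probe sets, 3 with the strict filter, 1 without a filter and 10 with the actin covariate. Those 10 are named above.

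Interferon response calls in CD4 cells ended with quantile normalization (adjusted p = 0.0882 with romidepsin and 0.111 with vorinostat) and with equal medians (0.179 and 0.276), over ranges of 0.00521 to 0.428 and 0.00673 to 0.408. The one with romidepsin also ended without a filter on dim genes, with a median of 0.04 rather than 0.51 (adjusted p = 0.0559). The neuronal calls held there at medians of at most 9.77e-05. The effector cytokine call in CD8 cells with romidepsin ended with both (0.0850 and 0.0956), as did the cholesterol call there (0.129 and 0.179, range 0.00169 to 0.675). No scaling moved the median change of all genes by more than 0.0899. Signal over background limits the rest: 38.5% to 40.9% of probe sets per array lay at the lowest value.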

Other observations

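Genes and values in this part, and the direct test of the drugs at their highest doses, were chosen after the results were seen.

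Lists were not tested at the highest doses. Of 22 T cell receptor signalling genes, 12 fell in CD4 cells with romidepsin and 7 with vorinostat (18 and 17 with the batch as a block), and 3 and 12 in CD8 cells (15 and 17). Of 17 chemokine receptor and adhesion genes 6 and 6 fell in CD4 cells (11 and 12 with the block), and 0 and 3 in CD8 cells (7 and 11). The actin 3' minus 5' difference was higher as well (1.55 and 0.97 in the batches of CD4 cells with romidepsin, against 0.94 and 0.78). At 10 nM the actin covariate took the median of T cell receptor genes from -1.10 to -0.41. That covariate rose with the drug, so a part of RNA quality stays open. The Gapdh difference was 0.24 and 0.09 at 30 nM, against 0.20 and 0.16 in the controls. In CD8 cells the inhibitory receptor gene Pdcd1 changed by -3.19 ± 0.75 with romidepsin at 30 nM and by -4.78 ± 0.75 with vorinostat at 10 µM (adjusted p = 0.0105 and 0.000321). The adaptor gene Lcp2, which relays T cell receptor signals, changed by -3.33 and -4.73, and Sla, which restrains that receptor, by -3.20 and -5.27. The NK-type receptor gene Klrd1 changed by -6.79 ± 1.83 with vorinostat (-8.91 and -4.67 in batches 1 and 2) and Klrc1 by -3.83 ± 0.96 with romidepsin (-6.12 and -1.54). The chemokine Cxcl10, induced by interferon, rose by 4.62 ± 0.68 (6.14 and 3.10 in the batches) and 6.95 ± 0.68 (7.68 and 6.22), Ccl5 by 4.68 and 5.26, and Plagl1 by 5.37 and 6.31.

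In CD4 cells at the highest doses the interleukin 7 receptor gene Il7r changed by -4.82 ± 1.39 with romidepsin and by -4.66 ± 1.39 with vorinostat (-6.01 and -3.63, and -5.79 and -3.52, in the batches). The cytokine genes Il4 (-5.04 ± 1.03) and Il24 (-5.79 ± 0.86) fell with romidepsin, and Serpinf1 with both (-5.79 and -6.13). Gimap3, of a family that supports lymphocyte survival, changed by -4.92 and -4.80, and Mlf1 rose by 4.37 and 3.98. Set against each other at these doses, 3 genes were lower with vorinostat in CD4 cells, and 5 with the block. In CD8 cells limma called none (403 at an unadjusted p under 0.05, smallest adjusted p = 0.118), and with the block 229 were higher and 588 lower.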
